A study of Mus musculus with 8 samples.

How the data were processed

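Intestinal crypts of 4 Tdp-43 conditional knockout mice (cKO) and 4 wild-type littermates (Ctrl), 8 weeks old, were released with EDTA and shaking and passed through a strainer, and total RNA was taken with TRIzol and made into Illumina libraries, per the labels' protocols. The groups follow the titles of the samples. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and CASAVA, without their roles or order. The genome build, the annotation release and the use of strand in counting are not given in the sources used here.

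The deposited table held 1 normalized signal value per gene and library, which the authors had made from gene counts by dividing by 1 factor per library, as the values show. Dividing each library's values by its smallest step gave whole reads for 100% of values in each of the 8 libraries, with a tolerance of 0.000100 reads. The recovered totals ranged from 21517596 to 29992110 reads on genes. The authors' deposited table also gave a log2 fold change, a p-value and an adjusted p-value per gene from a test it does not name, with 55 genes without a p-value. It called 1457 genes higher and 1468 lower, of which 932 and 1003 were also called here. The table held 29037 genes. Of their identifiers, 98.9% were found in GENCODE M21 on GRCm38, and of those 99.6% had identical coordinates. No libraries of a group agreed within sampling noise, the smallest chi-square per degree of freedom between 2 libraries being 29.3.

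The plan assumed gene counts, but the table holds normalized values, so the test planned for that case was used. Genes with a mean of at least 10 over the 8 libraries were tested with limma 3.58.1 (eBayes with trend and robust estimation, two-sided) on log2(value + 1) with the group as the only term. P-values were adjusted by Benjamini-Hochberg over the 16536 tested genes, with a threshold of 0.05. The added 1 pulls the fold changes of low genes toward 0, but they compare means of logs and can also exceed the ratio of the means. Reg3a had 5.30 on this scale and 4.04 in the authors' table. edgeR 4.0.16 on the recovered reads with TMM scaling, the quasi-likelihood test planned for counts, was run as an added alternative and called 993 genes higher and 909 lower, 909 and 898 of them also called by limma. For genes with at most 3 reads over a group the ratio per library total is given with a 95% exact interval, which covers counting error only.

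Gene lists for cell types, processes and gut regions, 44 in number, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.0100, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry, which tests whether members move one way on balance, were run beside it. The rule for named genes had 4 parts. It named Tardbp, then the 10 largest and 10 smallest log2 fold changes among called protein-coding genes that passed the filter on the mean and whose groups did not overlap, leaving out Xist, the Y chromosome and symbols that start with Gm or end in Rik. It then named up to 4 members of each described list by adjusted p with members moving against their list, and last Ripk3, Mlkl, Zbp1, Casp8, Rnaseh1, Lgr5, Olfm4, Lyz1 and Muc2. Some genes that the rule names are not reported here. Genes outside it are said to have been named after their values were seen, apart from those of a test set down before its result was seen.

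Besides the reported setting, 27 others were run, 24 of them planned and 3 added after the data were seen. They covered the pseudocount, filters on low values, protein-coding genes alone, X and Y chromosome genes left out, a test against a fold of 1.5, the replicate number as a block, scalings (TMM, RLE, upper-quartile and library totals), limma-voom, DESeq2 1.42.0 on recovered reads, both other list tests and each library left out. The test against a fold was run with limma in place of edgeR's, and the planned edgeR scalings on recovered reads. Lists were not run with that test or DESeq2.

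The tests were tried on simulated data for the comparison of 4 against 4, with counts drawn from negative binomial distributions at the real genes' means and dispersions and the real depths, in 3 runs with 200 changed genes each and 16493 to 16522 genes tested. Of genes changed by 1.5-fold, 2-fold and 4-fold, 12.4%, 51.7% and 84.3% were recovered, with 26 false calls in all. With no changed genes, 1 gene and 0 lists were called. Simulated genes vary independently, unlike real genes, so the list result does not carry over to the real lists. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.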

Results

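RNA was sequenced from crypt epithelium of the intestines of 8-week-old mice, 4 conditional knockouts of Tdp-43 (cKO) and 4 wild-type littermates (Ctrl), with 1 library per mouse as the labels give them. Crypts are the pits of the intestinal lining in which stem cells divide, and Tdp-43, encoded by Tardbp, is an RNA-binding protein of the nucleus. The deposited values are gene counts divided by 1 factor per library and are called normalized counts here. Recovered reads on genes came to between 21517596 and 29992110 per library. The first principal component held 36.9% of the variance and separated the groups. The comparison asked which genes differ in the crypt epithelium of Tdp-43 conditional knockouts, and the study's title names R-loops, mitochondria, necroptosis and intestinal inflammation. Levels are given as mean ± SD over the 4 libraries of a group, and log2 fold changes, on the log2(value + 1) scale, as cKO over Ctrl ± SE with the adjusted p of limma.

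Tardbp RNA was higher in the libraries labelled cKO than in Ctrl, the reverse of what loss of the whole transcript would give. Tardbp (ENSMUSG00000041459, chromosome 4, 148612382 to 148627019 on the minus strand, coordinates that equal those of GRCm38) had 6319, 6342, 5103 and 4900.2 normalized counts in Ctrl replicates 1 to 4. It had 11990.2, 10794, 11875 and 13269 in the libraries labelled cKO 1 to 4. The difference was larger than the spread within both groups (log2 fold change 1.09 ± 0.11, adjusted p = 0.00209). The value covers the whole gene and the deleted part is not given in the sources used here, so it checks nothing about the deletion, and every direction below is between the groups as labelled. Tested against a fold of 1.5, the adjusted p was 0.0896, the highest of a range from 8.28e-14 over the alternatives.

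**Figure D1:**
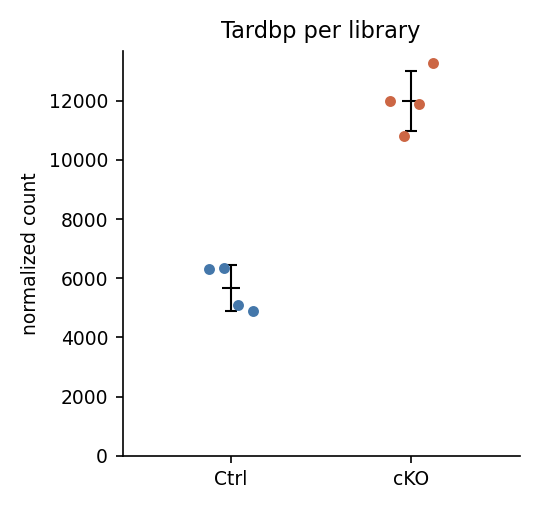
Tardbp normalized counts per library (y axis, from 0) in the Ctrl libraries and the libraries labelled cKO (x axis), with points for libraries, a horizontal mark for the mean and bars for the SD (n = 4). The lowest library labelled cKO, at 10794, lies above the highest Ctrl library, at 6342.

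In the libraries labelled cKO, 935 genes were higher and 1004 lower than in Ctrl, of 16536 tested. Changes of at least 2-fold made up 379 and 346 of these. The largest increases by the naming rule included the serine protease Prss22 (3.20 ± 2.42 in Ctrl and 278 ± 262 in cKO, log2 fold change 5.94 ± 0.73, adjusted p = 0.00359). They also included the stress-induced pseudokinase Trib3 (12.4 ± 6.10 in Ctrl and 422 ± 250.3 in cKO) and the neutrophil-attracting chemokine Cxcl2 (29.9 ± 32.3 in Ctrl and 423 ± 206 in cKO). Log2 fold changes were 4.36 for Mdfi, 4.31 for the membrane transporter Slc4a11, 4.21 for the peptide hormone Adm2 and 3.90 for the cationic amino acid transporter Slc7a3. The antimicrobial lectins Reg3a and Reg3d rose by 5.30 ± 1.13 and 5.09 ± 1.04 on the log2 scale, with the split of reads between these paralogs uncertain. Arhgap40 had 276 reads over the libraries labelled cKO and 3 over Ctrl, a ratio of 93.3 per library total (95% exact interval 31.6 to 455, counting error only). The largest decreases included Lrat, which esterifies retinol (212 ± 29.6 in Ctrl and 18.2 ± 15.1 in cKO, log2 fold change -3.76 ± 0.45, adjusted p = 0.00310). Others were the sulfotransferase Sult1a1 (6751 ± 421 in Ctrl and 931 ± 719.6 in cKO) and the butyrophilin-like Btnl1, which shapes intraepithelial T cells (1635 ± 326 in Ctrl and 205 ± 179 in cKO). Log2 fold changes were -3.82 for Pbld1, -3.53 for the organic anion transporter Slco2b1, -3.53 for the kinase Dclk3, -3.43 for Fndc5, -3.42 for Zmat4 and -3.17 for the inflammasome sensor Nlrp1b, which has close paralogs and is uncertain. The potassium channel Kcnj16 had 2 reads over the libraries labelled cKO and 176 over Ctrl, a ratio of Ctrl to cKO of 86.8 (95% exact interval 23.7 to 722, counting error only). Its Ctrl reads were uneven, with 36.5, 3.15, 11.4 and 117 normalized counts in replicates 1 to 4, so the ratio leans on Ctrl replicate 4. Scaled to library totals instead, 1329 genes were higher and 738 lower, so that 64.3% of calls were higher, against 48.2% as reported. Without Ctrl replicate 1, 2, 3 or 4, 490, 509, 379 or 515 genes were higher and 488, 548, 390 or 505 lower, and without cKO replicate 1 or 4, 427 or 469 were higher and 516 or 541 lower. Reg3a lost the call without Ctrl replicates 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0654). Reg3d lost the call without Ctrl replicate 3 or cKO replicate 1 (adjusted p up to 0.0622). Kcnj16 lost the call without Ctrl replicates 1 or 3 or cKO replicates 1 or 4 (adjusted p up to 0.0737).

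**Figure D2:**
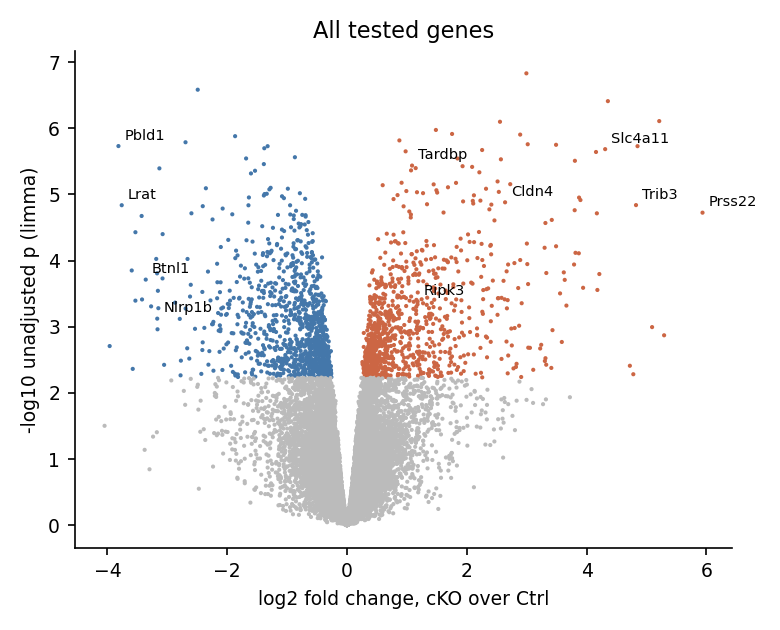
Each point is a tested gene, by log2 fold change of cKO over Ctrl (x axis) and -log10 of the unadjusted limma p (y axis), colored where the adjusted p was under 0.05. Of 16536 genes, 935 were higher and 1004 lower in the libraries labelled cKO.

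Of the gene lists with enough tested members, 43 in number, 12 were higher and 6 lower than other genes in the libraries labelled cKO by camera with its preset correlation. With an estimated correlation camera called 0 lists (4 at an unadjusted p under 0.05), while fry called 7 higher and 0 lower. Fry called cytokines, chemokines and NF-kB targets (fry adjusted p = 0.0108), fetal-like regenerative epithelium (0.0110), the integrated stress response (0.0170) and neutrophil (0.0256). These 4 were also the lists at an unadjusted p under 0.05 with an estimated correlation. The rest of fry's calls were enteric neuron and glia (0.0307), NRF2 antioxidant targets (0.0382) and p53 targets (0.0470). Of the 35 splits of the 8 libraries into 4 and 4, 17, the real one among them, gave as many list calls. The number of list calls thus does not set the real grouping apart.

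Genes of the integrated stress response, which ATF4 induces when translation is curbed, were higher in the libraries labelled cKO: 16 rose and 0 fell of 23 tested members (17 and 0 adjusted over the list alone). Their median log2 fold change was 1.21 (camera adjusted p = 1.51e-11, and adjusted p = 0.495 with an estimated correlation). Trib3 rose (log2 fold change 4.83 ± 0.57, adjusted p = 0.00310), as did the stress cytokine Gdf15 (118 ± 13.3 in Ctrl and 670.1 ± 245 in cKO, log2 fold change 2.41 ± 0.29, adjusted p = 0.00310). Increases were also seen in the amino acid transporter subunit Slc3a2 (0.74) and Psph, an enzyme of serine synthesis (1.45). Of p53 targets, 11 rose and 1 fell of 27 tested members (15 and 2 adjusted over the list alone). P53 targets had a median of 0.53 (camera adjusted p = 4.84e-06, and adjusted p = 0.679 with an estimated correlation). Phlda3, a repressor of AKT signalling, rose (49.4 ± 21.2 in Ctrl and 546 ± 249.7 in cKO, log2 fold change 3.42 ± 0.43, adjusted p = 0.00395), with the apoptosis effector Bax (0.99) and Sesn2 (0.96), whereas Sesn1 fell by 0.60 on the log2 scale. Gdf15 and Sesn2 stand in both lists. Of NRF2 antioxidant targets, 6 rose and 0 fell of 21 tested members (6 and 0 adjusted over the list alone). NRF2 antioxidant targets had a median of 0.31 (camera adjusted p = 0.000355, and adjusted p = 0.582 with an estimated correlation). They included heme oxygenase Hmox1 (77.1 ± 21.7 in Ctrl and 287 ± 69.0 in cKO, 1.90), the aldo-keto reductase Akr1b8 (0.83), the cystine transporter Slc7a11 (1.78), which also stands in the stress response list, and Gclc, which makes glutathione (0.63). Of immediate early and heat shock genes, 2 rose and 0 fell of 18 tested members (2 and 0 adjusted over the list alone), the transcription factor Fosl1 (2.46) and Ier3 (1.37). Their median was 0.35 (camera adjusted p = 0.00778, and adjusted p = 0.824 with an estimated correlation). Of the unfolded protein response of the endoplasmic reticulum, 0 rose and 0 fell of 16 tested members (0 and 0 adjusted over the list alone). Unfolded protein response had a median of 0.04 (camera adjusted p = 0.670). Sesn1 lost the call without Ctrl replicate 3 (adjusted p up to 0.0584). Immediate early and heat shock genes as a list lost the call without cKO replicates 1 or 2 (adjusted p up to 0.0635). Immediate early and heat shock genes had medians of 0.21 and 0.60 without cKO replicates 2 and 3. Unfolded protein response had medians of 0.07 and 0.01 without Ctrl replicates 2 and 4, and of -0.01, 0.26 and -0.03 without cKO replicates 1, 2 and 4.

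Cytokine genes and neutrophil markers were higher as lists in the libraries labelled cKO by camera with its preset correlation. Of cytokines, chemokines and NF-kB targets, 12 rose and 1 fell of 30 tested members (17 and 1 adjusted over the list alone). Cytokines, chemokines and NF-kB targets had a median of 1.24 (camera adjusted p = 3.17e-07, and adjusted p = 0.261 with an estimated correlation). Cxcl16 (127 ± 47.6 in Ctrl and 582 ± 135 in cKO, log2 fold change 2.23 ± 0.27, adjusted p = 0.00300) and the neutrophil attractant Cxcl1 (21.4 ± 8.98 in Ctrl and 176 ± 96.6 in cKO, 2.89) rose. The macrophage growth factor Csf1 (105 ± 14.2 in Ctrl and 209 ± 21.2 in cKO) and the adhesion molecule Icam1 (1.53) rose as well, and Ccl28, which attracts plasma cells, fell by 1.09. Of neutrophil markers, 6 rose and 0 fell of 9 tested members (9 and 0 adjusted over the list alone). Neutrophil had a median of 3.02 (camera adjusted p = 1.38e-05, and adjusted p = 0.495 with an estimated correlation). Retnlg (1.33 ± 2.67 in Ctrl and 19.7 ± 16.4 in cKO), the decoy receptor Il1r2 (5.28 ± 3.61 in Ctrl and 31.4 ± 19.5 in cKO) and the growth factor receptor Csf3r (12.3 ± 15.0 in Ctrl and 131 ± 125 in cKO) were low in Ctrl. Ly6g, of a family of similar genes and so uncertain, had 993 ± 366 in Ctrl and 9083 ± 6257 in the libraries labelled cKO. Of macrophage and dendritic cell markers, 1 rose and 0 fell of 17 tested members (7 and 0 adjusted over the list alone), the mannose receptor Mrc1 (0.87), with a median of 0.93 (camera adjusted p = 0.00351, and adjusted p = 0.824 with an estimated correlation). Of epithelial antimicrobial defence genes, 5 rose and 1 fell of 20 tested members (6 and 4 adjusted over the list alone). Epithelial antimicrobial defence had a median of 0.53 (camera adjusted p = 0.260). The siderophore-binding Lcn2 (24.9 ± 10.2 in Ctrl and 223 ± 176 in cKO, 2.80), Reg3a (5.30), the nitric oxide synthase Nos2 (1.44) and the calprotectin subunits S100a8 (4.72) and S100a9 (4.78), which the neutrophil list also holds and which were named after their values were seen, rose, while Pigr, which carries IgA across the epithelium, fell by 1.30. Ccl28 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 3 (adjusted p up to 0.0770). Retnlg lost the call without Ctrl replicates 1, 2 or 3 or cKO replicate 1 (adjusted p up to 0.0624). Il1r2 lost the call without Ctrl replicates 1, 2 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0905). Csf3r lost the call without Ctrl replicates 1, 2 or 3 or cKO replicates 1, 3 or 4 (adjusted p up to 0.102). Mrc1 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.107). Lcn2 lost the call without Ctrl replicates 2 or 3 or cKO replicate 4 (adjusted p up to 0.0622). Reg3a lost the call without Ctrl replicates 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0654). Nos2 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0840). S100a8 lost the call without Ctrl replicates 1, 2 or 3 or cKO replicates 1, 3 or 4 (adjusted p up to 0.107). S100a9 lost the call without Ctrl replicates 1, 2 or 3 or cKO replicates 1, 3 or 4 (adjusted p up to 0.119). With all libraries, S100a9 lost the call in 9, S100a8 in 7 and Csf3r in 6 of 17 other settings, S100a9 also in DESeq2. In Ctrl replicates 1 to 3, S100a8 and S100a9 had at most 2.10 and 1.22 normalized counts. In Ctrl replicate 4 they had 34.7 and 36.5, above cKO replicate 2 at 30.2 and 24.4, so the groups overlapped. Pigr lost the call without Ctrl replicates 1, 3 or 4 (adjusted p up to 0.0587). Epithelial antimicrobial defence had medians of 0.89 and 0.19 without Ctrl replicates 1 and 3, and of 0.30 and 0.81 without cKO replicates 1 and 2.

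Genes of antigen presentation were lower as a list in the libraries labelled cKO (median log2 fold change -0.78, camera adjusted p = 0.0150, and adjusted p = 0.824 with an estimated correlation), although 0 rose and 0 fell of 18 tested members (0 and 0 adjusted over the list alone). Of interferon-stimulated genes, 0 rose and 0 fell of 38 tested members (0 and 0 adjusted over the list alone). Interferon-stimulated genes had a median of -0.51 (camera adjusted p = 0.0533). Of cytosolic nucleic acid sensing genes, 1 rose and 1 fell of 19 tested members (1 and 2 adjusted over the list alone). Cytosolic nucleic acid sensing had a median of -0.22 (camera adjusted p = 0.290). The helicase Ddx41 rose (0.41), and the kinase Ikbke fell by 0.33. Of T cell and intraepithelial lymphocyte markers, 0 rose and 0 fell of 19 tested members (0 and 0 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.0611). Of B cell and plasma cell markers, 0 rose and 0 fell of 9 tested members (0 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.336). Antigen presentation as a list lost the call without Ctrl replicate 2 or cKO replicates 2 or 4 (adjusted p up to 0.135). Ddx41 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0850). Ikbke lost the call without Ctrl replicates 1, 2 or 3 or cKO replicate 1 (adjusted p up to 0.0682). Antigen presentation had medians of -0.42 without Ctrl replicate 2, and of -0.48 without cKO replicate 2. Interferon-stimulated genes as a list passed without Ctrl replicates 3 or 4 or cKO replicates 1 or 3 (adjusted p down to 0.000176). Interferon-stimulated genes as a list also passed with all libraries in 5 of 17 other settings (adjusted p down to 0.00613). Interferon-stimulated genes had medians of -0.19, -0.29 and -0.79 without Ctrl replicates 1, 2 and 4, and of -0.88, -0.20 and -0.18 without cKO replicates 1, 2 and 4. T cell and intraepithelial lymphocyte as a list passed without Ctrl replicates 1 or 4 or cKO replicate 3 (adjusted p down to 0.000108). T cell and intraepithelial lymphocyte as a list also passed with all libraries in 5 of 17 other settings (adjusted p down to 0.00378). T cell and intraepithelial lymphocyte had medians of -0.14 without Ctrl replicate 3, and of -0.19 and -0.88 without cKO replicates 2 and 3. Cytosolic nucleic acid sensing had medians of -0.07, -0.09 and -0.34 without Ctrl replicates 1, 2 and 4, and of -0.35 and -0.08 without cKO replicates 1 and 2. B cell and plasma cell had medians of 0.66, 0.51, 0.18 and -0.09 without Ctrl replicates 1, 2, 3 and 4, and of 0.48 and 0.16 without cKO replicates 2 and 3.

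Members of the necroptosis list, a form of cell death named in the study's title, changed in part. Of the list, 5 rose and 0 fell of 23 tested members (5 and 0 adjusted over the list alone). The kinase Ripk3 rose (1048 ± 277 in Ctrl and 2366 ± 558 in cKO, log2 fold change 1.18 ± 0.22, adjusted p = 0.0130), as did the death ligand Tnf (94.8 ± 39.2 in Ctrl and 283 ± 51.4 in cKO, 1.65), which the cytokine list also holds. So did its receptor Tnfrsf1a (0.35) and the protease Casp8, which restrains necroptosis (3315 ± 494 in Ctrl and 5051 ± 707 in cKO, log2 fold change 0.61 ± 0.13, adjusted p = 0.0205). The mitochondrial phosphatase Pgam5 (0.47), named after its values were seen, rose too. Mlkl, which breaches the membrane in necroptosis, had 1509 ± 527 in Ctrl and 1525 ± 692 in cKO (log2 fold change -0.03 ± 0.37, adjusted p = 0.968). The nucleic acid sensor Zbp1 had 3953 ± 1493 in Ctrl and 2566 ± 1554 in cKO (log2 fold change -0.78 ± 0.51, adjusted p = 0.365). The median of the list was -0.06 and its mean -0.00256, while camera's direction was upward (camera adjusted p = 0.694). Of the inflammasome and pyroptosis list, 2 rose and 6 fell of 23 tested members (6 and 7 adjusted over the list alone). Inflammasome and pyroptosis had a median of -0.22 (camera adjusted p = 0.156). The sensors Nlrp6 (9623 ± 1370.5 in Ctrl and 3925 ± 1214 in cKO, -1.33), Naip5 (-0.52) and Nlrp1b (-3.17), with uncertain reads for the last pair because of their paralogs, and the adaptor Pycard (-0.78) fell, and the pore-forming Gsdmd (0.42) and the sensor Nlrp3 (3.41) rose. Tnfrsf1a lost the call without Ctrl replicates 1 or 4 or cKO replicate 1 (adjusted p up to 0.0572). Casp8 lost the call without Ctrl replicates 3 or 4 (adjusted p up to 0.0646). Pgam5 lost the call without Ctrl replicates 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0734). Pycard lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.0944). Gsdmd lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0924). Nlrp3 lost the call without Ctrl replicates 1, 2 or 3 or cKO replicates 1, 3 or 4 (adjusted p up to 0.107). With all libraries, Nlrp3 lost the call in 6 of 15 other settings. Inflammasome and pyroptosis as a list passed with all libraries and no filter on low values (adjusted p = 0.0384). Zbp1 had a log2 fold change of -0.38 without cKO replicate 2. Mlkl had log2 fold changes of 0.07, 0.15, -0.07 and -0.26 without Ctrl replicates 1, 2, 3 and 4, and of -0.27, 0.21, -0.16 and 0.11 without cKO replicates 1, 2, 3 and 4. Necroptosis had medians of -0.01 and -0.09 without Ctrl replicates 2 and 4, and of -0.09, -0.03, -0.10 and 0.02 without cKO replicates 1, 2, 3 and 4.

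**Figure D3:**
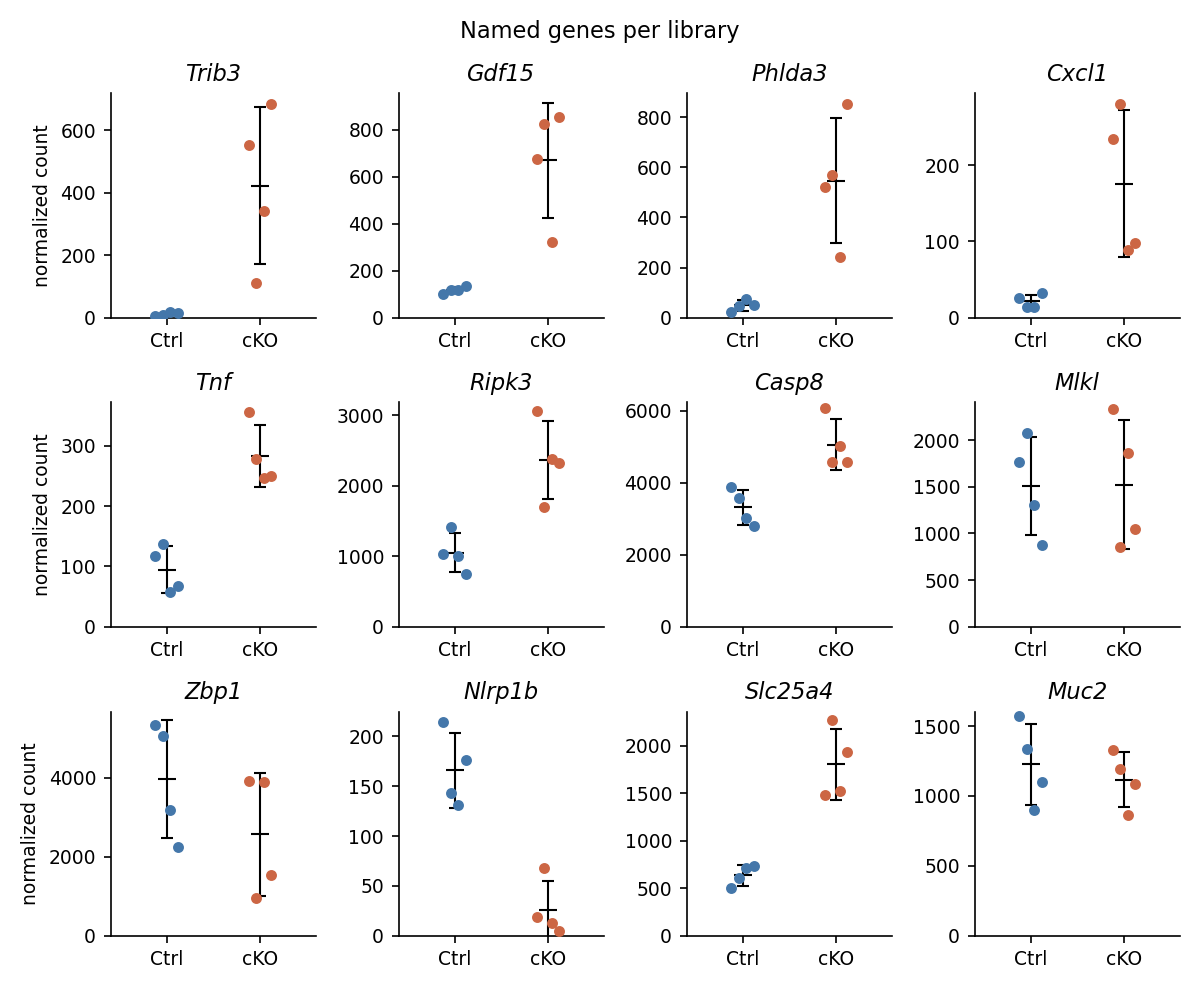
Normalized counts per library (y axes, from 0) of Trib3, Gdf15, Phlda3, Cxcl1, Tnf, Ripk3, Casp8, Mlkl, Zbp1, Nlrp1b, Slc25a4 and Muc2 in Ctrl and in the libraries labelled cKO (x axes), with points for libraries, a horizontal mark for the mean and bars for the SD (n = 4). Ripk3, Casp8 and Tnf lie higher in each library labelled cKO than in each Ctrl library, and the groups overlap for Mlkl, Zbp1 and Muc2.

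Genes of the nuclear-encoded respiratory chain, of fatty acid oxidation and of cholesterol synthesis were lower as lists in the libraries labelled cKO by camera with its preset correlation, and none of these lists passed with an estimated correlation. Mitochondrially encoded proteins were not called with all libraries. Of the nuclear-encoded respiratory chain, 1 rose and 6 fell of 78 tested members (1 and 6 adjusted over the list alone). Over all tested genes 11.7% passed in either direction, so the number of called members does not set this list apart. Nuclear-encoded respiratory chain had a median of -0.23 (camera adjusted p = 9.08e-08, and adjusted p = 0.824 with an estimated correlation). The complex I subunits Ndufc2 (2062 ± 281 in Ctrl and 1247 ± 157 in cKO, -0.72) and Ndufb2 (-0.57) and the succinate dehydrogenase subunit Sdhb (-0.56) fell, and Ndufa4 rose (0.44). Of fatty acid oxidation and PPAR-alpha targets, 0 rose and 3 fell of 18 tested members (0 and 6 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.0185, and adjusted p = 0.824 with an estimated correlation). Ehhadh (1384 ± 56.5 in Ctrl and 945 ± 139.6 in cKO, -0.56) and Acadm (-0.70), enzymes of fatty acid oxidation, fell. Of cholesterol synthesis genes, 0 rose and 3 fell of 23 tested members (0 and 5 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00410, and adjusted p = 0.824 with an estimated correlation). The members that fell were the reductase Dhcr7 (-0.46), the sterol carrier Stard4 (-0.49) and the synthase Hmgcs1 (-0.42). Of mitochondrially encoded proteins, 0 rose and 1 fell of 13 tested members (0 and 0 adjusted over the list alone), the cytochrome oxidase subunit mt-Co1 (-0.70), against a list median of 0.29 (camera adjusted p = 0.494). Of genes of mitochondrial dynamics, DNA and permeability, 1 rose and 2 fell of 27 tested members (1 and 2 adjusted over the list alone). Mitochondrial dynamics, DNA and permeability had a median of -0.13 (camera adjusted p = 0.186). The ADP/ATP carrier Slc25a4 rose (637 ± 109 in Ctrl and 1803 ± 373 in cKO, log2 fold change 1.49 ± 0.17, adjusted p = 0.00287), and the coactivators Ppargc1a and Ppargc1b fell by 0.82 and 0.66. Of mitochondrial ribosomal proteins, 2 rose and 4 fell of 76 tested members (2 and 4 adjusted over the list alone). Mitochondrial ribosomal proteins had a median of -0.01 (camera adjusted p = 0.852). Mrpl20 (0.60) and Mrps18b (0.46) rose, and Mrps9 (-0.52), Mrpl48 (-0.86), Mrps35 (-0.33) and Mrps31 (-0.38, named after its values were seen) fell. Sdhb lost the call without Ctrl replicate 3 (adjusted p up to 0.0565). Ndufb2 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0765). Fatty acid oxidation and PPAR-alpha targets as a list lost the call without Ctrl replicate 4 or cKO replicate 1 (adjusted p up to 0.0840). Ehhadh lost the call without Ctrl replicate 3 (adjusted p up to 0.0563). Acadm lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.119). Stard4 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 4 (adjusted p up to 0.0685). Hmgcs1 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.122). With all libraries, Hmgcs1 lost the call in 7, Acadm in 6 and Ppargc1a in 5 of 17 other settings. mt-Co1 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.114). Ppargc1a lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.117). Ppargc1b lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0699). Mrps18b lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0957). Mrps9 lost the call without Ctrl replicate 3 (adjusted p up to 0.0543). Mrpl48 lost the call without Ctrl replicates 3 or 4 or cKO replicate 4 (adjusted p up to 0.0690). Mrps35 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0870). Mrps31 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0947). Nuclear-encoded respiratory chain had a median of -0.14 without cKO replicate 1. Fatty acid oxidation and PPAR-alpha targets had a median of -0.15 without cKO replicate 1. Mitochondrially encoded proteins as a list passed without Ctrl replicate 3 (adjusted p = 0.0484). Mitochondrially encoded proteins had medians of 0.10, 0.08 and 0.61 without Ctrl replicates 1, 2 and 3, and of 0.56, 0.05 and 0.12 without cKO replicates 1, 3 and 4. Mitochondrial ribosomal proteins had medians of -0.02, 0.02 and -0.04 without Ctrl replicates 2, 3 and 4, and of -0.03, 0.05, -0.05 and -0.03 without cKO replicates 1, 2, 3 and 4.

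Genes that resolve R-loops, which are RNA-DNA hybrids with a displaced strand, changed little in number. Of the R-loop resolution and genome stability list, 1 rose and 0 fell of 37 tested members (0 and 0 adjusted over the list alone), the helicase Ddx21 (3003 ± 251 in Ctrl and 4254 ± 731 in cKO, 0.49), with a list median of 0.07 (camera adjusted p = 0.230). Rnaseh1, which digests the RNA of such hybrids, had 321 ± 17.0 in Ctrl and 343 ± 40.9 in cKO (log2 fold change 0.09 ± 0.12, adjusted p = 0.670). Of RNA-binding proteins and splicing factors other than Tardbp, 1 rose and 0 fell of 39 tested members (0 and 0 adjusted over the list alone), the splicing regulator Rbfox2 (0.45), with a median of 0.07 (camera adjusted p = 0.242). Of S phase and DNA replication genes, 1 rose and 1 fell of 33 tested members (1 and 1 adjusted over the list alone). S phase and DNA replication had a median of 0.28 (camera adjusted p = 0.0113, and adjusted p = 0.824 with an estimated correlation). Ccne1, a cyclin of S phase entry, rose (1.03), and the clamp loader subunit Rfc2 fell by 1.24. Of G2 phase and mitosis genes, 0 rose and 0 fell of 21 tested members (0 and 0 adjusted over the list alone). G2 phase and mitosis had a median of 0.13 (camera adjusted p = 0.459). Of cytosolic ribosomal proteins, 0 rose and 0 fell of 80 tested members (0 and 0 adjusted over the list alone). Cytosolic ribosomal proteins had a median of 0.07 (camera adjusted p = 0.0372, and adjusted p = 0.824 with an estimated correlation). Ddx21 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0920). Rbfox2 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 1 (adjusted p up to 0.0831). S phase and DNA replication as a list lost the call without Ctrl replicate 4 or cKO replicates 1 or 3 (adjusted p up to 0.161). Ccne1 lost the call without Ctrl replicates 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0830). Cytosolic ribosomal proteins as a list lost the call without Ctrl replicates 1 or 2 or cKO replicates 2, 3 or 4 (adjusted p up to 0.469). R-loop resolution and genome stability as a list passed without cKO replicate 2 (adjusted p = 0.0388). RNA-binding proteins and splicing factors other than Tardbp as a list passed without cKO replicate 2 (adjusted p = 0.0131). G2 phase and mitosis as a list passed without cKO replicate 2 (adjusted p = 0.00218). S phase and DNA replication had medians of 0.16 without Ctrl replicate 4, and of 0.15 and 0.45 without cKO replicates 1 and 2. Cytosolic ribosomal proteins had medians of 0.03, 0.02 and 0.15 without Ctrl replicates 1, 2 and 3. R-loop resolution and genome stability had medians of 0.11 without Ctrl replicate 1, and of 0.03, 0.17 and 0.11 without cKO replicates 1, 2 and 3. RNA-binding proteins and splicing factors other than Tardbp had medians of 0.04 without Ctrl replicate 4, and of 0.02, 0.16 and 0.05 without cKO replicates 1, 2 and 3. G2 phase and mitosis had medians of 0.20, 0.23, 0.03 and 0.06 without Ctrl replicates 1, 2, 3 and 4, and of 0.01, 0.32 and 0.03 without cKO replicates 1, 2 and 4.

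Markers of fetal-like regenerative epithelium, a state known after injury, were higher in the libraries labelled cKO: 8 rose and 0 fell of 18 tested members (11 and 0 adjusted over the list alone). Their median log2 fold change was 1.01 (camera adjusted p = 1.82e-07, and adjusted p = 0.349 with an estimated correlation). Annexin Anxa1 (3748 ± 252 in Ctrl and 7966 ± 1711 in cKO, log2 fold change 1.07 ± 0.13, adjusted p = 0.00359) rose. The keratin Krt7 (0.94), the EGF receptor ligand Ereg (78.1 ± 38.5 in Ctrl and 1298 ± 861 in cKO, 3.87) and the alarmin Il33 (2.52), which the cytokine list also holds, rose with it. Of enterocyte genes, 1 rose and 5 fell of 22 tested members (2 and 8 adjusted over the list alone). Enterocyte had a median of -0.33 (camera adjusted p = 0.0195, and adjusted p = 0.824 with an estimated correlation). The brush border enzymes Mgam (-0.85) and Dpp4 (-0.55) and the fatty acid binding protein Fabp2 (-1.45) fell, as did Mep1a (-1.22) and Slc5a1 (-0.44), named after their values were seen, and the triglyceride synthesis enzyme Dgat2 rose (1.47). Of enteroendocrine cell markers, 0 rose and 0 fell of 18 tested members (0 and 0 adjusted over the list alone). Enteroendocrine cell had a median of 0.39 (camera adjusted p = 0.0246, and adjusted p = 0.824 with an estimated correlation). Of crypt stem cell markers, 1 rose and 3 fell of 18 tested members (4 and 4 adjusted over the list alone). Crypt stem cell had a median of -0.15 (camera adjusted p = 0.276). Cdk6 (-0.55), the water channel Aqp4 (-1.37) and Rgmb (-0.72) fell, and Olfm4 rose from a low level (7.70 ± 2.67 in Ctrl and 24.3 ± 13.1 in cKO, log2 fold change 1.49 ± 0.41, adjusted p = 0.0484). Lgr5, which marks cycling stem cells, had 323 ± 89.8 in Ctrl and 188 ± 109 in cKO (log2 fold change -1.13 ± 0.65, adjusted p = 0.297). Enterocyte as a list lost the call without cKO replicates 1 or 4 (adjusted p up to 0.0762). Dpp4 lost the call without Ctrl replicate 1 (adjusted p up to 0.0515). Mep1a lost the call without Ctrl replicates 1, 3 or 4 (adjusted p up to 0.0622). Slc5a1 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.115). With all libraries, Slc5a1 lost the call in 8 of 17 other settings. Enteroendocrine cell as a list lost the call without Ctrl replicate 3 or cKO replicates 2 or 4 (adjusted p up to 0.110). Aqp4 lost the call without Ctrl replicate 3 (adjusted p up to 0.0520). Rgmb lost the call without Ctrl replicates 1, 2 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0833). Olfm4 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.118). Enterocyte had a median of -0.53 without cKO replicate 2. Crypt stem cell had a median of -0.06 without cKO replicate 2. Lgr5 had a log2 fold change of -0.40 without cKO replicate 2.

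Markers of goblet, Paneth and tuft cells and genes of epithelial junctions were not called as lists by camera with all libraries and the filter on low values as reported. Of goblet cell markers, 0 rose and 2 fell of 15 tested members (0 and 2 adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 0.313). The members that fell were Tpsg1 (-1.10) and Clca1 (-1.87), while the mucin Muc2 had 1228 ± 289.6 in Ctrl and 1117 ± 198 in cKO (log2 fold change -0.12 ± 0.19, adjusted p = 0.716). Of Paneth cell markers, 1 rose and 0 fell of 6 tested members (1 and 0 adjusted over the list alone), the protease Mmp7 (169 ± 81.2 in Ctrl and 996 ± 541 in cKO, 2.53), with a median of 0.35 (camera adjusted p = 0.694). Lysozyme Lyz1 had 20.1 ± 14.0 in Ctrl and 87.9 ± 57.3 in cKO (log2 fold change 1.76 ± 0.94, adjusted p = 0.261). Genes of the Defa family, to which several of the fixed Paneth markers belong, took at most 3.96e-05% of reads in any library. The list, with Mmp7, therefore says little about Paneth cells. Of tuft cell markers, 0 rose and 0 fell of 15 tested members (1 and 4 adjusted over the list alone). Tuft cell had a median of -0.53 (camera adjusted p = 0.113). Of epithelial junctions and keratins, 5 rose and 1 fell of 24 tested members (5 and 3 adjusted over the list alone). The tight junction gene Cldn4 (901 ± 238 in Ctrl and 5887 ± 2525 in cKO, log2 fold change 2.64 ± 0.30, adjusted p = 0.00307) and Krt20 (0.60) rose, as did F11r (0.29) and Krt18 (0.48), named after their values were seen, and Cldn15 fell by 0.87. The median of that list, -0.07, differed in sign from its mean of 0.0769 and from camera's upward direction (camera adjusted p = 0.795). Tpsg1 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.101). Clca1 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 3 (adjusted p up to 0.118). With all libraries, Clca1 lost the call in 8 of 17 other settings. Krt20 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1 or 3 (adjusted p up to 0.0853). F11r lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.112). Krt18 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.108). Cldn15 lost the call without Ctrl replicate 3 (adjusted p up to 0.0544). Goblet cell as a list passed without cKO replicate 4 (adjusted p = 0.0453). Tuft cell as a list passed without Ctrl replicate 2 or cKO replicate 4 (adjusted p down to 0.0138). Tuft cell as a list also passed with all libraries and no filter on low values (adjusted p = 0.0286). Lyz1 passed without cKO replicate 2 (adjusted p = 0.0163). Lyz1 also passed with all libraries in DESeq2 (adjusted p = 0.0256). Lyz1 had a log2 fold change of 2.72 without cKO replicate 2. Muc2 had log2 fold changes of 0.01, -0.07 and -0.26 without Ctrl replicates 1, 2 and 3, and of -0.21 and -0.00345 without cKO replicates 1 and 3. Goblet cell had medians of -0.03, -0.07 and -0.18 without Ctrl replicates 1, 2 and 3, and of -0.05 and -0.20 without cKO replicates 3 and 4. Paneth cell had medians of 0.12 and 0.61 without Ctrl replicates 2 and 4, and of 0.66 and -0.18 without cKO replicates 1 and 2. Tuft cell had a median of -0.32 without cKO replicate 1. Epithelial junctions and keratins had medians of -0.04 without Ctrl replicate 3, and of -0.10 and -0.02 without cKO replicates 2 and 4.

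Markers of other cell types and of gut regions were measured as well. Of fibroblast markers, 0 rose and 1 fell of 11 tested members (0 and 1 adjusted over the list alone). The member that fell was the growth factor receptor Pdgfrb (206 ± 12.4 in Ctrl and 88.5 ± 25.9 in cKO, log2 fold change -1.26 ± 0.23, adjusted p = 0.0118), and the median was -0.90 (camera adjusted p = 0.0552). Of endothelium markers, 0 rose and 0 fell of 4 tested members (0 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.532). Of smooth muscle markers, 0 rose and 0 fell of 5 tested members (0 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.718). Of enteric neuron and glia markers, 1 rose and 0 fell of 5 tested members (1 and 0 adjusted over the list alone). The member that rose was the receptor kinase Ret (56.7 ± 6.93 in Ctrl and 259 ± 84.7 in cKO, log2 fold change 2.12 ± 0.25, adjusted p = 0.00287). The list had a median of 1.17 (camera adjusted p = 0.0463, and adjusted p = 0.582 with an estimated correlation). Of exocrine pancreas markers, 0 rose and 1 fell of 8 tested members (0 and 1 adjusted over the list alone), the colipase Clps (-2.30), against a median of 1.41 (camera adjusted p = 0.459). The erythroid cell list had too few tested members for a test. Of distal small intestine genes, 0 rose and 1 fell of 6 tested members (0 and 2 adjusted over the list alone), the bile acid binding protein Fabp6 (-2.10), with a median of -0.49 (camera adjusted p = 0.0421, and adjusted p = 0.824 with an estimated correlation). Of proximal small intestine genes, 0 rose and 1 fell of 5 tested members (1 and 2 adjusted over the list alone), the iron exporter Slc40a1 (-0.88), with a median of -0.20, a mean of 0.00445 and a downward direction in camera (camera adjusted p = 0.649). Of colon genes, 0 rose and 1 fell of 9 tested members (0 and 1 adjusted over the list alone), with a median of 0.02, a mean of -0.0210 and a downward direction in camera (camera adjusted p = 0.718). Enteric neuron and glia as a list lost the call without Ctrl replicates 1 or 2 or cKO replicates 1, 2 or 4 (adjusted p up to 0.124). Clps lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1 or 3 (adjusted p up to 0.0887). Distal small intestine as a list lost the call without Ctrl replicate 1 or cKO replicates 1 or 4 (adjusted p up to 0.0893). Slc40a1 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 1 (adjusted p up to 0.108). Fibroblast as a list passed without Ctrl replicates 1 or 3 or cKO replicates 3 or 4 (adjusted p down to 0.00927). Fibroblast as a list also passed with all libraries in 8 of 17 other settings (adjusted p down to 0.0146). Fibroblast had medians of -0.46 without Ctrl replicate 4, and of -0.26 without cKO replicate 2. Distal small intestine had a median of -0.98 without cKO replicate 2. Endothelium had medians of -0.14 and -0.07 without Ctrl replicates 1 and 4, and of -0.38 without cKO replicate 3. Smooth muscle had medians of -0.31 and -0.07 without Ctrl replicates 2 and 4, and of -0.32 without cKO replicate 3. Exocrine pancreas had medians of 0.92 without Ctrl replicate 2, and of 2.33 without cKO replicate 4. Proximal small intestine had medians of -0.03, 0.08, 0.18 and 0.19 without Ctrl replicates 1, 2, 3 and 4, and of 0.02 without cKO replicate 2. Colon had medians of -0.13, -0.06 and 0.22 without Ctrl replicates 1, 3 and 4, and of 0.21, -0.32, 0.15 and 0.08 without cKO replicates 1, 2, 3 and 4.

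**Figure D4:**
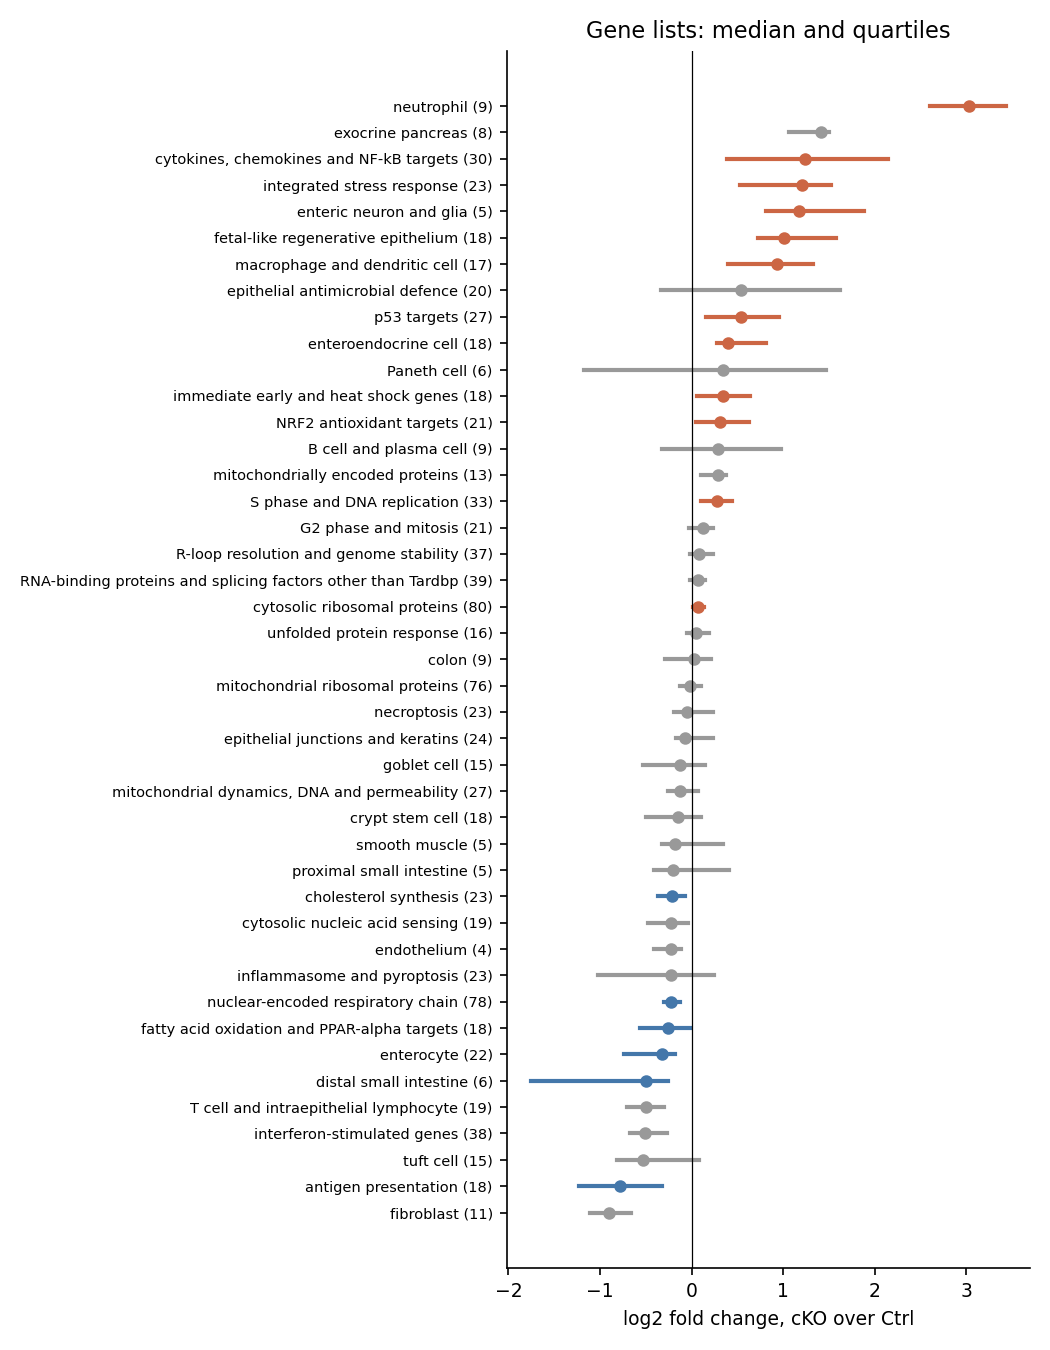
Medians (points) and quartiles (lines) of the log2 fold changes, cKO over Ctrl (x axis), of the tested members of each list (y axis, with the number of members in brackets), orange for lists higher and blue for lists lower by camera with its preset correlation and grey for the others. The neutrophil list has the highest median, 3.02.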

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

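The tests of Tardbp, of epithelial share, of the neutrophil markers, of Ly6g and of the sex of cKO replicate 3 as a source of the group difference were chosen only after the results were seen. Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave 1939 genes past the threshold, against at most 62 in any other. This argues against chance for the gene count, although 1 of 35 is the smallest share the splits can give. The other splits mix the groups, which can lower their counts, and a cause shared by the libraries of a group was not tested. For the lists 17 of 35 splits, the real one among them, gave as many calls, with up to 26 in another split. Chance cannot be excluded for the number of list calls, though splits that mix the groups can keep part of a group difference.

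Tardbp RNA was higher in the libraries labelled cKO. The lowest of them was 1.70 times the highest Ctrl library, which argues against a single wrong label or a swap of single libraries, and the lowest log2 fold change over the scaling alternatives was 1.08, which argues against the scaling. All 8 labels exchanged between the groups and RNA of a recombined allele counted over the rest of the gene (whole-gene log2 fold change 1.09) cannot be told apart, since the table gives 1 value per library for the whole gene and none for its parts. A response of Tardbp expression to the knockout stays open as an untested biological explanation.

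Neutrophil markers, macrophage markers and cytokine genes were higher as lists in the libraries labelled cKO by camera with its preset correlation, and none of these lists passed with an estimated correlation. The neutrophil median exceeded the higher of the T cell and fibroblast medians by 3.52 log2 units, which argues against a lower share of epithelial cells that raises all other cell types alike. Neutrophil RNA in the crypt fraction stays open, since the rise of 6 of 9 neutrophil markers is the pattern itself and tests nothing. For Ly6g, whose reads are uncertain, the ratio to S100a8 (counted as at least 3) ran from 7.69 to 590 over the libraries. Both genes were higher on average in cKO than in Ctrl, though S100a8 was higher in Ctrl replicate 4 (34.7) than in cKO replicate 2. The 2 genes did not move together among the cKO libraries. There, replicate 2 had the highest Ly6g (17824) and the lowest S100a8 (30.2), and replicate 4 the lowest Ly6g (3991) and the highest S100a8 (519). This argues against neutrophil RNA with a fixed ratio of these genes as the only source of the Ly6g reads across these libraries. Whether neutrophil RNA with a varying ratio is the only source cannot be told, since the ratio in neutrophils is not given in the sources used here. Inflammation in the conditional knockouts and a difference in dissection stay open as untested.

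Xist, the RNA that silences an X chromosome, was at 32.1 normalized counts in cKO replicate 3, far from the other cKO libraries at 24091 to 30892. Xist was named after its values were seen, while a test of genes that escape this silencing was set down before its result was seen. The median log2 difference of the escape genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x in cKO replicate 3 from its group mates was -0.464, the lowest of the 8 libraries. A single X chromosome, with or without a Y, would give such values. The deposited entries on the Y chromosome are not protein coding and had reads in libraries with high Xist too. They summed to 371 in cKO replicate 3, below the others at 999 to 2718. Every deposited gene had reads in some library. Protein-coding Y genes thus either had no reads, which would go against a Y, or were left out beforehand, and the sources used here do not say which. The sex of this library is not the source of the group difference, since 1755 genes passed the threshold without it.

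Of 300 groups of 4 values, 19 had 1 library far from the others, where chance gives about 1 in 20. In cKO replicate 1, Olfm4 had 43.8 (16.6 to 19.1 in the others), Anxa1 had 10529 (6995 to 7228 in the others) and Pigr had 38179.7 (84124 to 94677 in the others). In cKO replicate 2, Lgr5 had 30.2 (210.001 to 281 in the others), Lyz1 had 6.83 (98.4 to 141 in the others) and Gsdmd had 6958 (5197 to 5279 in the others). In cKO replicate 3, Sesn2 had 554 (896 to 972 in the others), and mitochondrial rRNA took 0.215% of reads, against 0.0326% to 0.0508%. In Ctrl replicate 1, Arhgap40 had 0 (0.889 to 1.05 in the others) and Pgam5 had 355 (292 to 301 in the others). In Ctrl replicate 2, Ppargc1b had 1483 (1620.02 to 1632 in the others), Pbld1 had 47.3 (96.1 to 99.8 in the others) and Fndc5 had 161 (253 to 254 in the others). In Ctrl replicate 3, Olfm4 had 3.79 (8.40 to 9.73 in the others), Rgmb had 1783 (2259 to 2351 in the others) and Stard4 had 9077 (7729.7 to 7822 in the others). In Ctrl replicate 4, Rfc2 had 1115 (1448 to 1466 in the others) and Retnlg had 5.34 where the others had 0, all in normalized counts with the range of the other libraries of the group.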

How the results depend on the processing

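The edgeR test with TMM, limma on reads rescaled by TMM and limma on reads scaled to library totals were chosen after the data were seen. Tardbp stayed higher in the libraries labelled cKO in every setting, with log2 fold changes of 1.02 to 1.17 (1.02 to 1.14 without single libraries). Tested against a fold of 1.5, its log2 fold change of 1.09 had an adjusted p of 0.0896, and 52 genes were higher and 24 lower, since that test asks for more than a difference. DESeq2 called 1462 genes higher and 1479 lower, and the cause was not tested. The authors' deposited table had nearly the same counts, 1457 and 1468. Its Tardbp log2 fold change, 1.081, was that of DESeq2 as well, so neither is a separate check on the other. With 1 library left out, 379 to 1347 genes were higher and 390 to 1385 lower, the highest without cKO replicate 2 and the lowest without Ctrl replicate 3, and 9 to 12 lists were higher and 4 to 9 lower. With no filter on low values 11 lists were lower. With an estimated correlation camera called 0 lists higher and 0 lower (4 at an unadjusted p under 0.05), and fry 7 higher and 0 lower, causes that were not tested. Of the 135 named genes that passed, 69 passed without each library in turn wherever they were still tested (Zmat4 was not in every such setting), and 66 lost the call without at least 1 library. Over the settings with all libraries, named genes had the direction and side of the threshold reported in 2174 cases, lost the threshold in 239, gained it in 1 and changed sign in 6, and lists had camera's direction and side of the threshold as reported in 649, lost the threshold in 44, gained it in 20 and changed camera's direction in 3. The lists that gained it were fibroblast in 8 settings, interferon-stimulated genes in 5, T cell and intraepithelial lymphocyte in 5, and tuft cell in 1 and inflammasome and pyroptosis in 1, both with no filter. Besides the estimated correlation and fry, enteric neuron and glia lost it in 5, cytosolic ribosomal proteins, distal small intestine and enteroendocrine cell in 3, 3 and 3, and enterocyte in 1. Among further named genes, Slc40a1 lost the call with all libraries in 7 settings, and Olfm4, Ikbke, Mrps35 and Fars2 in 5 each. Rgmb, mt-Co1, Mrc1, Clps, Mrps31, Hars2 and Gsdmc3 lost it in 4 each, the test against a fold of 1.5 included. With the replicate number as a block, 821 genes were higher and 924 lower, 1476 of all of them shared with the reported calls, and 12 lists were higher and 9 lower. Under the block 16 named genes lost the call. They were Olfm4, Rgmb, Ccne1, mt-Co1, Acadm, Nos2, Ikbke, Ddx41, Mrc1, Slc5a1, F11r, Krt18, Mrps35, Mrps18b, Rars and Slc38a9. Nothing in the labels says that a shared number marks a shared litter or day. Same-numbered libraries had correlations of 0.318, -0.106, 0.123 and 0.323 in their deviations from the group means, so not all of them deviate together and the numbers were not taken as pairs. The libraries numbered 1, 3 and 4 correlated best with their own number in the other group and those numbered 2 did not, a hint from the data and not the design.

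The following changes of direction were in results that passed no threshold as reported, and the cause was not tested. Mlkl was above 0 with edgeR under RLE (0.0191), upper-quartile (0.0252), library totals (0.0955) and TMM (0.0237), DESeq2 (0.0157) and limma on library totals (0.0529). The median of endothelium was 0.228 with no filter, and that of mitochondrial ribosomal proteins 0.0763 (edgeR) and 0.0670 (limma) on library totals. With 1 library left out, Mlkl ranged from -0.272 to 0.210 and Muc2 from -0.261 to 0.00537. For lists whose direction in camera changed with 1 library left out, medians ranged from -0.375 to -0.0707 for endothelium, -0.0515 to 0.0485 for mitochondrial ribosomal proteins and -0.213 to 0.186 for proximal small intestine. They ranged from -0.322 to 0.219 for colon, 0.00986 to 0.319 for G2 phase and mitosis and -0.0263 to 0.257 for the unfolded protein response. The ranges were -0.105 to -0.0209 for epithelial junctions and keratins and -0.102 to 0.0160 for necroptosis. Medians also crossed 0 in some settings with camera's direction kept, over all settings from -0.181 to 1.25 for Paneth cell, -0.0859 to 0.986 for B cell and plasma cell and -0.322 to 0.0994 for smooth muscle. Over all settings the median of epithelial junctions and keratins ran from -0.105 to 0.0184. At this depth and spread the simulated recovery of 1.5-fold changes was 12.4%. Each simulated run held 200 changed genes, while 1939 genes passed the threshold in the real data. The Benjamini-Hochberg adjustment is less strict where more genes change, so recovery in the real data can be higher and was not measured. A missing call still does not show that a gene is unchanged.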

Other observations

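Members of some gene families passed the test of single genes. These families, and all members named here other than Ereg, were chosen after their values were seen, so their counts and medians describe them and no test of a family as a group is given. Of cytochrome P450 and conjugating enzymes, which modify drugs and steroids, 1 rose and 20 fell of 84 tested members (median log2 fold change -0.45). The glucuronosyltransferase Ugt2b5 (-2.66) and the carboxylesterase Ces1d (798 ± 429 in Ctrl and 119 ± 91.9 in cKO, -2.87) fell, and Sult4a1 rose (3.49). Of cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 3 rose and 0 fell of 20 tested members (median log2 fold change 0.38). The changed members were Aars (3292 ± 196 in Ctrl and 4901 ± 868 in cKO, 0.56), Hars (0.51) and Rars (0.50). Of their mitochondrial counterparts, 0 rose and 4 fell of 17 tested members (median log2 fold change -0.14). The changed members were Lars2 (-0.41), Hars2 (-0.38), Wars2 (-0.58) and Fars2 (-0.41). Of amino acid transporters, 6 rose and 3 fell of 33 tested members (median log2 fold change 0.26). Slc7a5 rose (631 ± 83.1 in Ctrl and 1814 ± 576 in cKO, 1.47), and Slc6a14 (-1.07), Slc1a1 (-1.99) and Slc38a9 (-0.61) fell. Aars lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.0752). Hars lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0758). Rars lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 3 or 4 (adjusted p up to 0.110). Lars2 lost the call without Ctrl replicates 1, 2 or 3 or cKO replicates 1 or 4 (adjusted p up to 0.0647). Hars2 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 4 (adjusted p up to 0.0805). Wars2 lost the call without Ctrl replicates 1, 2 or 3 or cKO replicate 4 (adjusted p up to 0.0926). Fars2 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1, 2 or 4 (adjusted p up to 0.122). Slc38a9 lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0805).

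Structural and signalling families also held members that passed. Of keratins, 8 rose and 2 fell of 20 tested members (median log2 fold change 0.72). Krt36 rose (2.05), and Krt84 (-1.68) and Krt222 (-1.28) fell. Of EGF receptor ligands, 3 rose and 0 fell of 6 tested members (median log2 fold change 0.98). The changed members were Ereg (3.87), Areg (1.71) and Btc (1.38). Of the gasdermin C family, near-identical genes with uncertain reads, 0 rose and 2 fell of 6 tested members (median log2 fold change -2.57). The changed members were Gsdmc4 (-3.05) and Gsdmc3 (-2.43). Of mitochondrial transfer RNAs, 3 rose and 0 fell of 10 tested members (median log2 fold change 0.30). The changed members were mt-Te (14.7 ± 8.80 in Ctrl and 457 ± 262 in cKO, 4.85), mt-Ty (2.28) and mt-Tc (1.34), all uncertain because they overlap or adjoin other mitochondrial genes and the use of strand is not given in the sources used here. Of the Reg family, 2 rose and 0 fell of 6 tested members (median log2 fold change 0.59). Of claudins, 1 rose and 1 fell of 11 tested members (median log2 fold change -0.16). Krt222 lost the call without Ctrl replicates 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.0638). Areg lost the call without Ctrl replicates 1, 3 or 4 or cKO replicates 1 or 2 (adjusted p up to 0.0849). Btc lost the call without Ctrl replicate 3 (adjusted p up to 0.0529). Gsdmc4 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicate 1 (adjusted p up to 0.108). With all libraries, Gsdmc4 lost the call in 6 of 17 other settings. Gsdmc3 lost the call without Ctrl replicates 1, 2, 3 or 4 or cKO replicates 1 or 4 (adjusted p up to 0.114).

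A hypothesis set down before its result was seen held that genes with a long genomic span are lower in the libraries labelled cKO, as Tdp-43 is known to protect long transcripts in neurons. Spearman's rho of log2 fold change and span was -0.0238 across 13415 tested protein-coding genes, which are not independent replicates, and -0.0498 to 0.00664 with 1 library left out. The data thus argue against a trend over the whole range of spans. A correlation over all genes can miss a change limited to the longest ones. Noticed only afterwards, 10.1% of genes were lower in each of the 2 deciles of longest span, against 4.85% to 7.38% in the other deciles, a difference that was not tested.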
